A study of Mus musculus with 8 samples.

How the data were processed

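Per the labels, total RNA of mouse bone marrow-derived macrophages was hybridised to Affymetrix Mouse Gene ST arrays, 1 array per sample. Bone marrow cells were differentiated for 6 days with 15% L929-conditioned medium, a source of the macrophage growth factor CSF1, and then kept without CSF1 for 18 hours. The submitters' processing notes name Affymetrix Expression Console and Transcriptome Analysis Console; their versions, the summarisation algorithm and the scale of the values are not given in the sources used here.

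The value table used here listed 41345 distinct probe set identifiers against 8 arrays. All of its 330760 value cells were empty, so 0 cells held a measurement. The table was prepared for this work from the series' value table, and whether the values were already missing before that step is not known here. The empty cells therefore describe this copy of the table, and not the arrays or the values the submitters produced. Scanner files were not analysed here. The table was read with Python 3.11.15, which counted the filled cells per array. Probe sets were matched to GEO's platform annotation, which can be old: 23521 carried 1 gene symbol, 1814 carried several and 16010 were unnamed here.

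The design was fixed before the data were examined. It set 4 arrays of macrophages with floxed Tsc2 alleles and Cre recombinase against 4 control arrays with limma, and 27 gene lists with camera. None of these tests was run, under any setting, because the table used here held no value to test.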

Results

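Gene expression was to be compared between macrophages of 2 genotypes. The control group held 4 arrays from mice with floxed Tsc2 alleles and no Cre recombinase. The other group held 4 arrays from mice with the same floxed alleles and Cre expressed from the LysM locus. This genotype is meant to delete Tsc2 in myeloid cells. Tsc2 encodes a subunit of the complex that restrains the kinase mTORC1.

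No expression level, fold change or test result is reported for this comparison. Each of the 8 arrays had 0 filled cells among its 41345 probe sets in the value table used here. The level of Tsc2 itself, planned as a check of the genotype labels, was not examined either. Among probe sets annotated with exactly 1 gene symbol, 1 names this gene. A probe set for a whole gene averages exons inside and outside the deleted part. The size of its change would therefore not give the share of deletion.

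Across the 27 lists fixed for the comparison, with 448 memberships, 406 memberships matched a probe set annotated with exactly 1 gene symbol. By this rule 17 of 20 members of the glycolysis list were matched, 17 of 21 of the cholesterol synthesis list, 20 of 20 of the list of inflammatory cytokines and chemokines, and 3 of 9 of the list of erythroid and megakaryocyte markers. A member without such a match can still be measured by a probe set that carries several symbols or another name. These counts describe the annotation and the matching rule, and say nothing about expression in either genotype.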

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

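No comparison of expression was computed, because all value cells of the table used here were empty, and the limma and camera settings fixed before the data were examined were not run. No paired analysis was possible because the table used here held no values for the arrays, although they share replicate numbers between the groups. The array titles number the replicates within each genotype and do not state whether arrays with the same number form a pair. The shared numbers alone therefore do not show that the design was paired. Scanner files were not analysed here. The one quantity that was recomputed concerns the array's annotation and not expression. Its settings were not planned and were chosen after the empty table had been seen. Of 448 list memberships, 406 matched a probe set with 1 gene symbol, 424 matched when probe sets with several symbols were also counted, and 407 matched when older and newer symbols were also accepted.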
